A study of Mus musculus with 8 samples.

How the data were processed

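RNA was measured in MII oocytes of C57BL/6 females at postnatal day 42, with 4 libraries of wild-type and 4 of Esrp1-deficient animals. Per the labels' protocols, oocytes were lysed in tubes of 15 and full-length cDNA was made with Smart-seq2, a method that primes on poly(A) tails and does not mark the strand of the RNA. The design text names 4 biological replicates per group, but not whether a tube held oocytes of a single animal, so p-values measure the spread between tubes.

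The deposited values are FPKM per gene, per the file headers, made by the authors from reads on GRCm38, the build named in the submitters' processing notes. The aligner, the counting tool and the annotation release are not given in the sources used here. Each library listed the same 24860 Ensembl genes, none of them at 0 in all 8 libraries, and 24812 had a symbol in GENCODE M21. FPKM relate each gene's reads to its length and to the library total. A change in a few abundant genes therefore shifts all others, and values are relative levels, not molecules per egg.

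Multiplied by the length of a gene's exons in M21, FPKM fell on whole multiples of a step per library, within a tolerance of 0.02 of a read, for about 90% of the values above 0. This gave the reads per gene for 22629 genes, and a search over lengths gave them for 1744 more, 24373 in all. The implied library totals were 24910433 to 32337966 reads, and the reads found summed to between 103.6% and 104.1% of them, so the total used by the authors was not the sum over genes. An FPKM of 1 in a transcript of 1 kb stood for 24.9 to 32.3 reads. Reads are not independent molecules, since PCR copies were not marked.

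Genes with a mean of at least 1 FPKM over the 8 libraries (8021) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend, genotype as the only term, two-sided tests and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. A fold change on this scale understates the change of low genes. Gene lists, 30 fixed before the data were examined, were tested with camera and a preset correlation of 0.01 where at least 5 genes were tested (26 lists), adjusted over the lists. None of the 4 list calls holds with an estimated correlation. Counts adjusted over the list alone were within 1 per direction of those over all genes except for the checkpoint and kinetochore list (8 higher, 8 lower), the anaphase-promoting complex list (1 and 1) and the ribosomal protein list (2 and 1). Measures per library were compared by exact permutation over all 70 arrangements. Count-based tools were left out of the main comparison, since the deposited unit is not a count, and a voom fit on recovered reads was added among the alternatives. The limma steps were tested on simulated data with the WT means and a spread smoothed over expression level (8148 genes tested). They recovered 28.6% of 63 genes changed 1.5-fold, 77.8% of 63 changed 2-fold and 100% of 61 changed 4-fold, with 9 false calls among 137. Far fewer genes changed there than passed in the real data, and the simulated libraries were independent, so these rates need not hold here.

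Genes are named by a rule fixed before the data were examined: Esrp1 and Esrp2; the 12 largest rises and 12 largest falls among genes past the threshold with non-overlapping groups, leaving out predicted, clone-named and unnamed loci; up to 4 members with the smallest p of each list discussed by name; and for markers of other cells the 4 with the highest level. Genes named beyond it, with mt-Rnr1 and mt-Rnr2, H2-Aa, Cd68, Lyz2 and those of the closing section among them, were chosen after their values were seen. Not every gene picked by the rule is described in the text. Which 16 lists are discussed by name was also decided after the data were seen. The small zygotic activation list was dropped from these, and with it Eif1ad and Sp110, unchanged genes whose sign turned in some alternatives. For 82 named genes, the share of 50-base stretches found in transcripts of other M21 genes and the overlap with exons of other genes were computed, and a share above 20% is given beside the gene. Other genes in the text, such as Mterf1a and those of the closing section's marker lists, were not checked, so a missing share there has no meaning.

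Same-numbered libraries of the groups deviated together. The correlation of their deviations from the group means over genes was 0.226 to 0.317 in all 4 pairs, and their mean of 0.267 was the highest of the 24 possible pairings. Unlike numbers came as high in some cases, with 0.402 for WT replicate 4 and Esrp1_KO replicate 1 and 0.252 for WT replicate 3 and Esrp1_KO replicate 2, both above the values of these WT libraries with their own number (0.261 and 0.226). The numbers, taken from the labels, were therefore used as pairs in alternatives and in comparisons of same-numbered libraries. The main fit and the exact permutation tests did not use them. No label gives a shared litter or day. The split of replicates 1 and 4 from replicates 2 and 3, shared by both groups, could also raise these correlations, so pairing by number is not firm. On a principal component holding 17.6% of the variance, replicates 1 and 4 lay apart from replicates 2 and 3 in both groups; the leading component (56.7%) parted the genotypes. With the replicate number as a block, 3406 genes passed (1376 higher, 2030 lower). Pearson correlations of log2 values were 0.961 to 0.979 within WT, 0.950 to 0.981 within Esrp1_KO and 0.895 to 0.937 between them. No 2 libraries of a group agreed as closely as copies of a single library would (chi-square of their reads per degree of freedom at least 36.6).

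Alternatives were 2 other pseudocounts, no filter, a filter at 5 FPKM, 4 other scalings, robust and unmoderated variance, library weights, the replicate block and leaving out each library. Added after seeing the data were limma voom on the recovered reads, replicates 1 and 4 or 2 and 3 alone, a common total of nuclear genes, and leaving out both WT replicate 1 and Esrp1_KO replicate 3. Exon use and splicing were not analysed, since the files give 1 value per gene. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.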

Results

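Oocytes arrested in metaphase of the second meiotic division (MII oocytes), the mature eggs of the mouse, were profiled from 6-week-old females. These were wild-type (WT) or labelled Esrp1 knockout (Esrp1_KO), and ESRP1 protein was not measured. ESRP1 is an RNA-binding protein that controls alternative splicing in epithelial cells. Each group had 4 libraries, described by the submitters as biological replicates, and each library was made from a tube of 15 oocytes. The comparison asks which transcripts of the mature egg differ between these groups. The read total behind each library, worked out from the deposited values, lay between 25018182 and 28932109 reads in WT and between 24910433 and 32337966 in Esrp1_KO, with no separation of the groups (n = 4 each, exact two-sided permutation p = 0.514). Values below are FPKM as mean ± SD with n = 4 per group, and fold changes are Esrp1_KO over WT unless a log2 value is given.

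The targeted gene, Esrp1 (ENSMUSG00000040728, chromosome 4, 11331933 to 11386783 in GRCm38, minus strand), was lower in each Esrp1_KO library than in each WT library. Its level was 17.5 ± 1.42 FPKM in WT, with 16.2 to 19.5 across libraries, and 3.30 ± 0.68 FPKM in Esrp1_KO, with 2.31 to 3.83 across libraries, or 18.8% of the WT mean. The log2 fold change was −2.12 ± 0.15 (SE, adjusted p = 1.32e-05, limma), and the exact two-sided permutation p of 0.0286 was the smallest that 4 against 4 libraries can give. Between 417 and 739 reads per Esrp1_KO library still fell on the gene, against 2710 to 3469 per WT library. Values per gene cannot show on which exons these reads lay. The paralog Esrp2 stayed below the expression filter and held 0 to 20 reads per library, except 84 reads (0.734 FPKM) in WT replicate 1.

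The egg transcriptome differed widely between the genotypes. Of 8021 genes tested, 2961 passed an adjusted p of 0.05 (limma), 1111 higher and 1850 lower in Esrp1_KO, and of these 295 rose and 589 fell by at least 1 on the log2 scale. Protein-coding genes made up 2538 of the changed genes, and predicted or clone-named loci, which are only counted here, 140 of those higher and 322 of those lower. In 2952 tested genes (36.8%) the 4 values of one group all lay on one side of the 4 of the other, where chance gives 2.86%. The balance of directions depended on scaling. Lower genes were 62.5% of the changed genes with FPKM as deposited, 49.1% with TMM scaling (1523 higher, 1468 lower), 51.1% with quantile normalization (1482 higher, 1546 lower) and 48.6% with median-ratio scaling (1551 higher, 1467 lower). These scalings moved the median log2 fold change of all genes from −0.06 to between 0.03 and 0.05, and a common total of nuclear genes moved it to −0.115. The sign of small changes therefore depends on scaling, up to a list median of −0.125 (p53 and apoptosis genes), which turned to 0.007 with TMM. Both genotypes also shared a split of replicates 1 and 4 from replicates 2 and 3. Within replicates 1 and 4 alone 2014 genes passed (675 higher, 1339 lower), and within replicates 2 and 3 alone 1448 (569 higher, 879 lower).

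The gene with the largest rise on the log2(FPKM + 1) scale was Itm2a, an integral membrane protein gene on chromosome X (107397099 to 107403376), from 0.148 ± 0.18 to 12.5 ± 1.45 FPKM. The autophagy receptor Sqstm1 rose 7.85-fold (2.98 ± 1.43 to 23.4 ± 6.23 FPKM), the centromere factor Mis18a 7.78-fold (4.29 ± 0.72 to 33.4 ± 12.3) and the DNA break repair factor Trp53bp1 5.49-fold (14.1 ± 1.996 to 77.3 ± 30.3). Also among the largest rises were the activation antigen Cd69 (10.1-fold), the hexosamine enzyme Gnpda1 (8.90-fold), the centriole protein Cetn2 (5.20-fold), the nuclear NF-kappa-B inhibitor Nfkbiz (4.995-fold), the mitochondrial import protein Mtx2 (5.40-fold), Mfhas1 (15.02-fold, from 0.335 ± 0.041 FPKM) and the proton pump subunit Atp6v1g1 (4.86-fold).

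The largest fall on the log2(FPKM + 1) scale, though not by ratio, was that of Nras, a small GTPase gene on chromosome 3 (103058285 to 103067914), from 44.2 ± 12.6 to 3.68 ± 1.37 FPKM, or 0.083 of the WT level. The chemokine receptor Cxcr3 fell to 0.071 of its WT level (11.9 ± 1.81 to 0.839 ± 0.72 FPKM), the retinoic acid-making enzyme Aldh1a2 to 0.078 (14.4 ± 2.51 to 1.12 ± 0.43) and Epb41l5, a cytoskeletal adaptor on chromosome 1, to 0.094 (19.4 ± 1.72 to 1.83 ± 0.35). Cth, an enzyme that makes cysteine, fell from 30.6 ± 5.14 to 3.98 ± 0.64 FPKM, and Slc25a13, the mitochondrial aspartate-glutamate carrier, from 11.3 ± 1.17 to 1.19 ± 0.58. Cd300c (9.23 ± 3.76 to 0.838 ± 0.50) and Tmem161b (18.2 ± 1.19 to 2.72 ± 0.77) were also among the 12 largest falls, as were mt-Cytb and mt-Nd2, described below. Mterf1b (15.1 ± 0.98 to 1.504 ± 0.47) and Xlr5c (6.44 ± 0.49 to 0.446 ± 0.41) completed them, with 61.3% and 84.4% of their 50-base stretches shared with other genes.

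**Figure D1:**
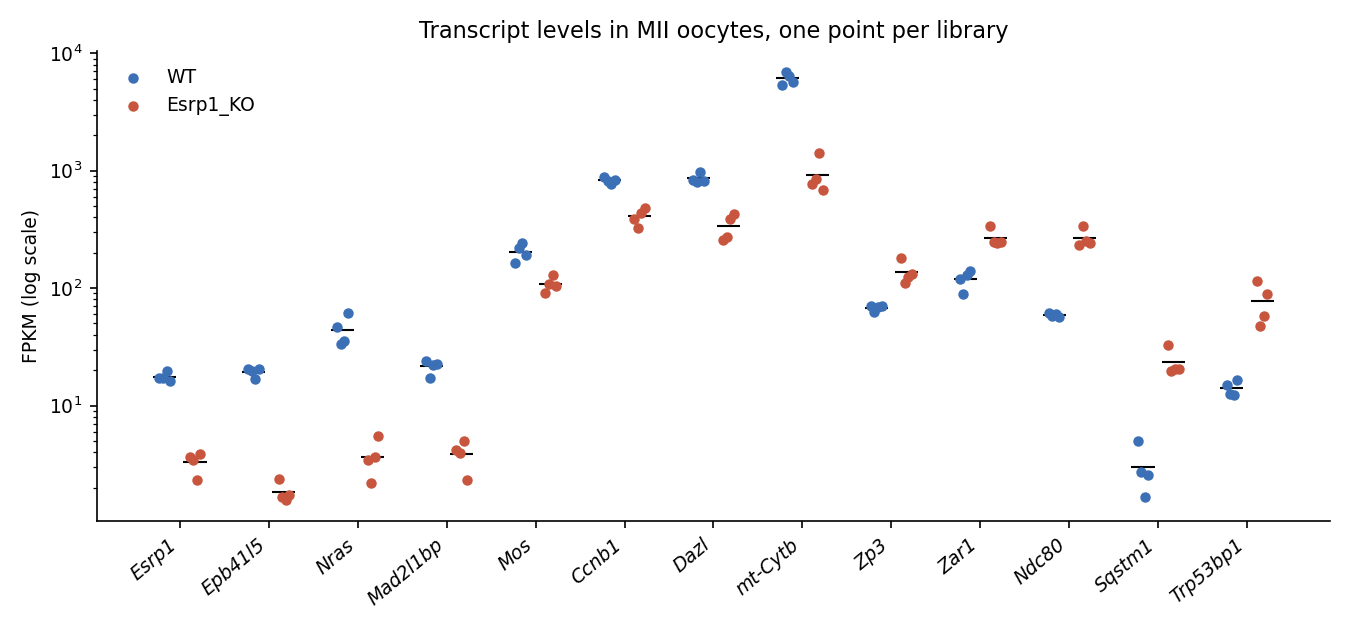
FPKM of 13 named genes on a logarithmic axis, with 1 point per library (4 WT, blue; 4 Esrp1_KO, red) and a black line at each group mean. The points of the groups do not overlap for any gene shown, from Esrp1 (17.5 against 3.30 FPKM) to Trp53bp1 (14.1 against 77.3 FPKM).

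Transcripts of the mitochondrial genome were lower in Esrp1_KO as a group. Of 15 tested, 14 fell and none rose, with a median log2 fold change of −1.95 (camera adjusted p = 2.11e-07 with a preset correlation; adjusted p = 0.538 with an estimated correlation). Cytochrome b (mt-Cytb) fell from 6106 ± 700 to 926 ± 329 FPKM, the complex I subunits mt-Nd2 from 1061 ± 25 to 183 ± 56 and mt-Nd4 from 707 ± 53 to 172 ± 44, and the cytochrome oxidase subunit mt-Co1 from 2788 ± 134 to 734 ± 172. Of these, mt-Nd4 and mt-Co1 share 62.2% and 51.1% of their 50-base stretches with other annotated genes. The mitochondrial ribosomal RNAs differed less, mt-Rnr2 with a log2 fold change of −0.79 (adjusted p = 0.0274, limma) and mt-Rnr1 with −0.87 (adjusted p = 0.0975, not past the threshold). Together these transcripts held 5.20 ± 0.17% of the summed FPKM in WT and 1.33 ± 0.35% in Esrp1_KO (exact two-sided permutation p = 0.0286, the smallest possible with 4 against 4). Adjusted over the list alone, 15 fell.

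Nuclear genes for subunits of the respiratory chain moved the other way. Of 42 tested, 12 rose, none fell and 30 did not pass, with a median log2 fold change of 0.40 (camera adjusted p = 0.00104 with a preset correlation; adjusted p = 0.538 with an estimated correlation). Adjusted over the list alone, 11 rose and none fell. The cytochrome oxidase subunits Cox6c and Cox5b rose 4.17-fold (2.71 ± 0.67 to 11.3 ± 4.81 FPKM) and 2.97-fold (3.95 ± 1.61 to 11.7 ± 5.54), the ATP synthase subunit Atp5f1 2.17-fold (6.62 ± 1.07 to 14.4 ± 3.33) and the complex I subunit Ndufv1 1.86-fold (1.14 ± 0.22 to 2.12 ± 0.027). Glycolysis and pyruvate genes gave 6 higher and 2 lower of 15 tested, and did not pass as a list (camera adjusted p = 0.134).

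Genes with exons reported to depend on ESRP proteins in epithelia, a list fixed from general knowledge and read here at gene level only, were lower in Esrp1_KO. Of 20 tested, 9 fell, none rose and 11 did not pass (median log2 fold change −0.32; camera adjusted p = 0.0129 with a preset correlation and adjusted p = 0.538 with an estimated correlation; 9 fell when adjusted over the list alone). Epb41l5, given above, and the transcription factor Grhl1 (3.95 ± 0.43 to 0.064 ± 0.032 FPKM) fell most. The endocytic adaptor Numb fell to 0.342 of WT (5.62 ± 0.999 to 1.92 ± 0.51) and Ccdc50 to 0.440 (12.99 ± 1.01 to 5.71 ± 1.07). The list did not pass when only genes with a mean of at least 5 FPKM were tested (camera adjusted p = 0.0729). Other splicing factors went both ways, with 12 higher and 13 lower of 75 tested (camera adjusted p = 0.236). Among them the splicing regulators Ptbp3 (13.5 ± 1.27 to 6.72 ± 0.75 FPKM), Srsf5 (27.9 ± 3.69 to 15.1 ± 0.84) and Rbm47 (2.81 ± 0.99 to 0.378 ± 0.29) fell, and the U1 snRNP protein gene Snrnp70 rose (12.02 ± 0.40 to 21.996 ± 3.17).

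Several oocyte-specific regulators and egg coat genes rose, though neither list passed. Of 28 oocyte transcription and identity genes 7 rose and 2 fell (camera adjusted p = 0.0843; the list passed with no filter, 0.0134, with sample quality weights, 0.0183, without WT replicate 3, 0.0401, without Esrp1_KO replicate 1, 0.0221, and with replicates 1 and 4 alone, 0.0267). Its median difference between same-numbered libraries ran from −0.023 (replicate 1) to 0.414 (replicate 4), so the sign is not firm. The transcription factors Nobox and Lhx8 rose 2.07-fold (25.9 ± 1.97 to 53.5 ± 4.67 FPKM) and 2.65-fold (16.4 ± 2.38 to 43.4 ± 11.4), and Zar1, a maternal mRNA-binding protein, rose 2.26-fold (119 ± 22 to 269 ± 47), with 28.4% of its 50-base stretches shared with other genes. Dazl, an RNA-binding translation regulator, fell to 0.391 of WT (859 ± 77 to 336 ± 83). Of 11 zona and fertilization genes 3 rose, all of them zona pellucida proteins of the egg coat, and none fell (camera adjusted p = 0.139). Zp3 rose 2.02-fold (68.0 ± 3.97 to 137 ± 31), Zp2 1.72-fold (44.9 ± 2.65 to 77.1 ± 14.6) and Zp1 2.02-fold (30.3 ± 7.29 to 61.3 ± 26.0). The call of Zp1 (log2 fold change 0.95, adjusted p = 0.0232, limma) was lost without WT replicate 3 (0.75, adjusted p = 0.0609), and, with about the same fold change, with no filter (adjusted p = 0.0779), with no moderation across genes (0.0758), with replicates 1 and 4 alone (0.132) and with replicates 2 and 3 alone (0.0665). The sperm-egg fusion gene Cd9 had 5.17 ± 2.94 FPKM in WT and 9.05 ± 3.28 in Esrp1_KO and did not pass (adjusted p = 0.106, limma), but did without WT replicate 1 (adjusted p = 0.0260) and with replicates 2 and 3 alone (0.0292). Of 26 maternal effect genes 9 rose and 4 fell (median log2 fold change 0.196, camera adjusted p = 0.134; with replicates 1 and 4 alone the list passed, with 0.351 and 0.0267), among them Uhrf1, which maintains DNA methylation (50.04 ± 6.61 to 88.8 ± 11.3), and the NLR-family genes Nlrp4c (10.5 ± 0.32 to 19.5 ± 2.85) and Nlrp4a, the last of which fell (281 ± 38 to 159 ± 14). Between same-numbered libraries the median difference of the maternal effect list ran from −0.063 (replicate 2) to 0.485 (replicate 1).

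Transcripts that drive meiotic maturation went in both directions. In the list of cyclin B, CDK1 and metaphase arrest genes 4 rose and 4 fell of 33 tested (camera adjusted p = 0.280). Those that fell include cyclins Ccnb1 (828 ± 46 to 408 ± 67 FPKM, with 23.4% of its 50-base stretches shared) and Ccnb3 (22.5 ± 1.10 to 10.6 ± 2.03) and the kinase Mos (204 ± 35 to 108 ± 16), while Fbxo5, which restrains the anaphase-promoting complex, rose (96.5 ± 9.04 to 159 ± 2.92). Of 18 mRNAs described as dormant until maturation, a list that shares Mos, Ccnb1 and Dazl with those above, 5 fell and 1 rose (camera adjusted p = 0.511). The riser was the spindle factor Tpx2 (107 ± 3.23 to 149 ± 6.61). Priming was on poly(A) tails, whose length was not measured, so a fall of these mRNAs need not mean fewer molecules. Factors of mRNA decay gave 7 higher and 9 lower of 33 (camera adjusted p = 0.892). Cpeb1 (71.8 ± 12.1 to 151 ± 31), which controls polyadenylation of dormant mRNAs, the m6A reader Ythdf2 (30.5 ± 4.68 to 63.0 ± 14.1) and Pabpc1l, an oocyte poly(A)-binding protein (6.37 ± 0.23 to 15.5 ± 6.09), rose, and Marf1 fell (17.6 ± 3.09 to 9.36 ± 1.33).

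Kinetochore and spindle genes held some large single changes, and neither list passed. Of 34 checkpoint and kinetochore genes 6 rose and 8 fell (camera adjusted p = 0.546). Ndc80, which attaches kinetochores to microtubules, rose 4.50-fold (59.2 ± 2.38 to 266 ± 47 FPKM) and the chromosomal passenger kinase Aurkb 2.63-fold (7.63 ± 1.18 to 20.03 ± 3.37). Mad2l1bp, which silences the spindle checkpoint, fell to 0.178 of WT (21.5 ± 2.93 to 3.84 ± 1.11) and the centromere protein gene Cenpc1 to 0.284 (7.91 ± 0.91 to 2.24 ± 0.54). Of 56 spindle genes 11 rose and 6 fell (camera adjusted p = 0.139; the list passed with replicates 1 and 4 alone, 0.0303). The microtubule organizers Mzt1 (127 ± 10 to 48.9 ± 6.42) and Pcnt (27.8 ± 4.97 to 11.2 ± 0.90) fell, while Tubgcp3 (0.689 ± 0.24 to 3.30 ± 0.74) and Tuba1c (24.7 ± 4.30 to 78.0 ± 19.7) rose, the last with 52.7% of its 50-base stretches shared with other genes. Of 25 cohesion and recombination genes 8 fell and 3 rose (camera adjusted p = 0.7998). The cohesin subunit Stag1 (1.92 ± 0.32 to 0.775 ± 0.068), the synaptonemal complex-related Sycp2l (61.1 ± 4.70 to 35.5 ± 2.27) and the shugoshin Sgo2a (6.57 ± 0.17 to 3.46 ± 0.40) fell, and Syce2 rose (38.1 ± 1.57 to 59.7 ± 9.13). Exons of another gene on the opposite strand cover 35.04% of Sgo2a, and strand was not marked by the library type. The anaphase-promoting complex gave 4 higher and 1 lower of 18 (camera adjusted p = 0.236), and actin and polar body genes 8 higher and 6 lower of 30 (camera adjusted p = 0.280).

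Among regulators of chromatin and DNA methylation 10 of 30 rose and 2 fell, with a median log2 fold change of 0.23 (camera adjusted p = 0.0298 with a preset correlation; adjusted p = 0.538 with an estimated correlation; 10 and 2 when adjusted over the list alone). The histone deacetylase Hdac2 rose from 19.7 ± 1.69 to 37.9 ± 5.79 FPKM, the demethylase Kdm1b from 17.2 ± 2.01 to 37.0 ± 9.14 and the insulator protein Ctcf from 14.1 ± 2.35 to 24.8 ± 0.51, while the demethylase Kdm4a fell from 6.96 ± 1.23 to 2.89 ± 0.46. The list did not pass without WT replicate 1 (camera adjusted p = 0.0808), without Esrp1_KO replicate 2 (0.0638), with quantile normalization (0.0551), with a mean of at least 5 FPKM (0.104) or with neither WT replicate 1 nor Esrp1_KO replicate 3 (0.108). Signalling and junction genes that link the oocyte to its follicle fell in 8 of 21 and rose in none, but did not pass as a list (camera adjusted p = 0.134), except with no filter (0.02445). They include N-cadherin Cdh2 (3.57 ± 0.30 to 1.02 ± 0.32), the scaffold Dlg1 (10.9 ± 0.52 to 4.54 ± 0.24) and the catenins Ctnna1 (53.2 ± 9.10 to 29.2 ± 2.48) and Ctnnb1 (50.3 ± 6.57 to 29.7 ± 5.90).

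Of 22 stress response genes 7 rose and 3 fell (median log2 fold change 0.122, camera adjusted p = 0.134; with replicates 2 and 3 alone the list passed, with 0.336 and 0.0471). Between same-numbered libraries the list's median difference ran from −0.058 (replicate 1) to 0.451 (replicate 2). Chaperones of the endoplasmic reticulum parted. Hsp90b1 rose 2.12-fold (83.7 ± 6.50 to 178 ± 10 FPKM) and Hspa5 fell (29.9 ± 1.51 to 18.1 ± 2.76). The stress-induced transcription factor Ddit3 rose (1.01 ± 0.33 to 2.94 ± 0.35) and the cytosolic co-chaperone Dnajb1 fell (18.0 ± 4.56 to 5.60 ± 1.55). Cytosolic ribosomal proteins gave 5 higher and 2 lower of 42 and proteasome subunits 5 and 1 of 29 (camera adjusted p = 0.134 and 0.129). Both of these lists passed without Esrp1_KO replicate 1 (camera adjusted p = 0.0221 and 0.0231) and with replicates 2 and 3 alone (0.0111 and 0.0289), and the proteasome list with no filter (0.0435). The ribosomal median log2 fold change, 0.135, turned to −0.0879 with replicates 1 and 4 alone and to −0.0195 without Esrp1_KO replicate 2. The proteasome median, 0.169, shrank to 0.0187 and 0.000756 in these runs. Between same-numbered libraries both medians were below 0 for replicate 1 (−0.498 and −0.022) and above 0 for replicates 2, 3 and 4, so neither sign is firm. The p53 and apoptosis list gave 3 and 3 of 23, PI3K and mTOR genes 5 and 2 of 20 and sterol genes 1 and 1 of 9 (camera adjusted p = 0.856, 0.428 and 0.927). In these last 3 the median log2 fold change was below 0 (−0.12, −0.02 and −0.20) while the test pointed up. Between same-numbered libraries their median differences reached 0.057, 0.226 and 0.069, so the sign is not firm. Of 4 zygotic activation genes tested, too few for a list test, 1 rose.

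**Figure D2:**
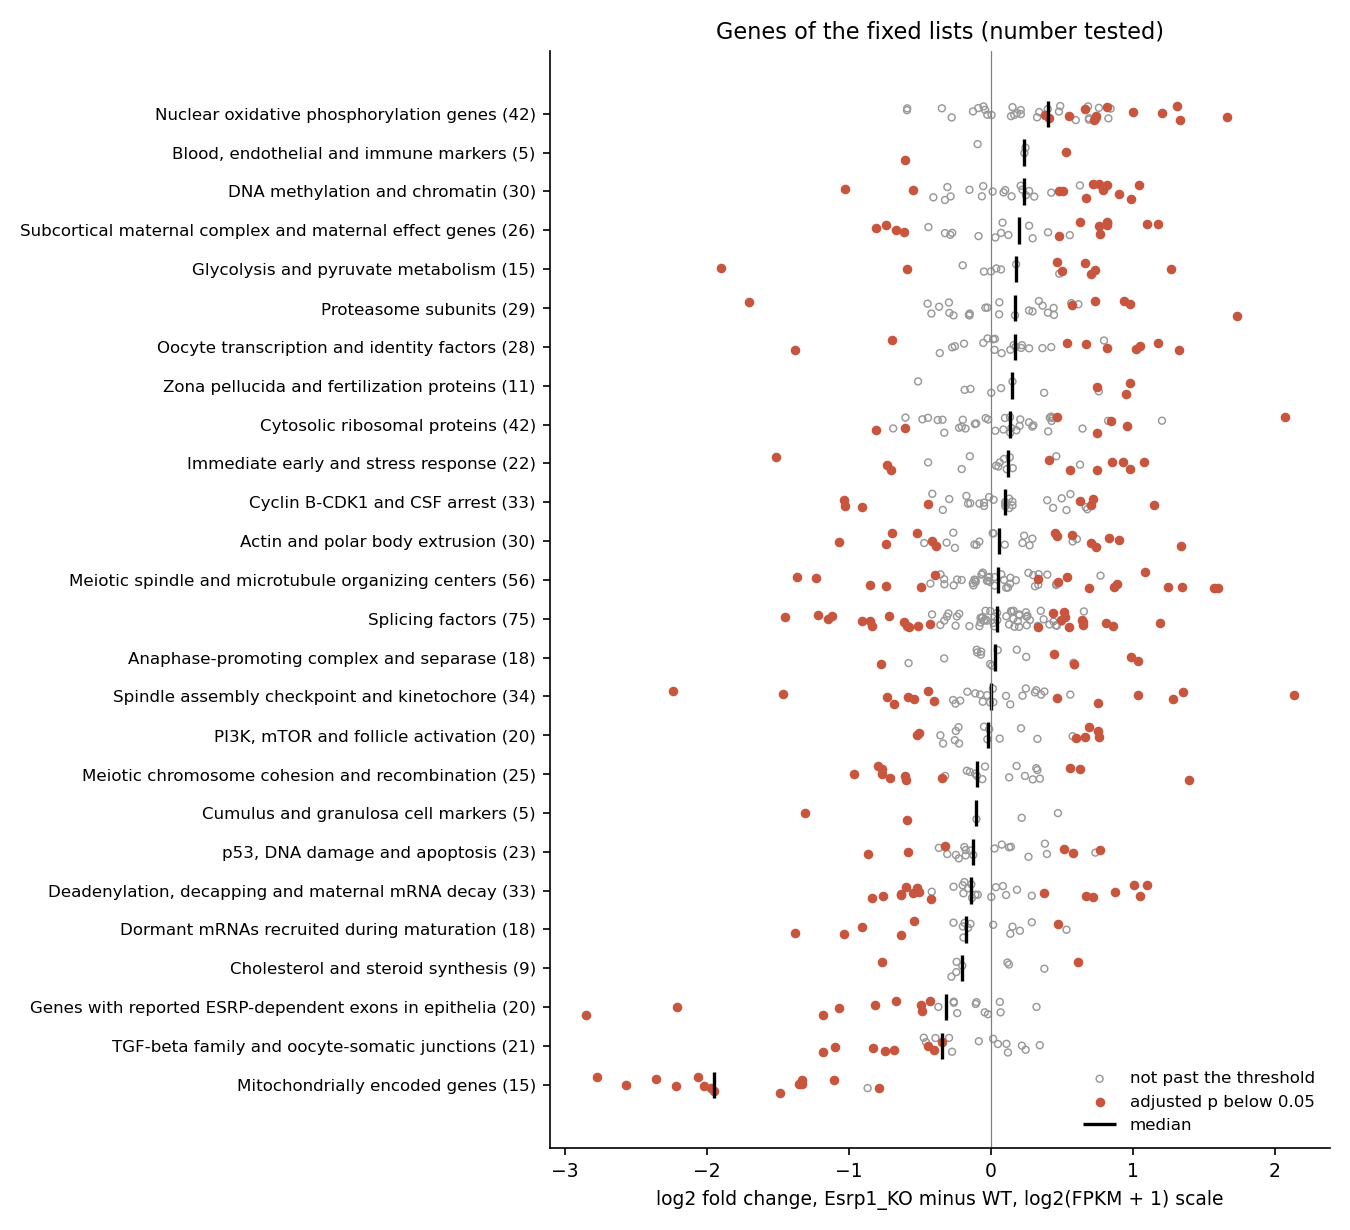
Log2 fold changes (Esrp1_KO minus WT, on the log2(FPKM + 1) scale) of the genes of the 26 lists with at least 5 tested genes, 1 point per gene, filled where the adjusted p was below 0.05 (limma), with a black line at each list's median. Medians ran from −1.95 for mitochondrially encoded genes to 0.40 for nuclear oxidative phosphorylation genes, and those of 8 lists near 0 changed sign under another scaling.

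At a level of at least 1 FPKM, with FPKM as deposited, fewer genes were detected in Esrp1_KO. The count was not repeated with another scaling. The balance of directions depended on scaling, so this difference may depend on it too. There were 8122 ± 219 genes per WT library and 7662 ± 114 per Esrp1_KO library (exact two-sided permutation p = 0.0286, the smallest possible). At 0.1 FPKM the groups overlapped (13792 ± 801 against 13236 ± 87, exact permutation p = 0.171), and at 5 FPKM the difference did not pass (4316.5 ± 69 against 4139.5 ± 86, exact permutation p = 0.0571). The number of genes at 0 was 7247 ± 2020 in WT and 7289 ± 366 in Esrp1_KO (exact permutation p = 0.971). For the cut at 1 FPKM, a paired exact sign-flip test over the 4 replicate numbers cannot go below its p of 0.125. The 10 most abundant genes of a library held 20.4 ± 0.81% of the summed FPKM in WT and 23.1 ± 0.68% in Esrp1_KO (exact permutation p = 0.0286). Neither this test nor those of Esrp1 and the mitochondrial share used the replicate numbers, and a paired sign-flip test would have the same floor of 0.125 for them.

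Markers of other cells of the ovary and oviduct were near the floor. Median levels of the listed granulosa, theca and stroma, blood and immune, and epithelial markers were at most 0.102 FPKM in either group. The exceptions in the granulosa list, Rgs2 (576 ± 37 in WT, 540 ± 83 in Esrp1_KO) and Serpine2 (148 ± 16 and 172 ± 19), did not pass, while Cyp19a1 (6.10 ± 0.71 to 1.87 ± 0.39) and Kitl (3.27 ± 0.54 to 1.83 ± 0.19) fell (limma). As lists, granulosa markers gave 2 lower of 5 tested and blood and immune markers 1 higher and 1 lower of 5 (camera adjusted p = 0.651 for both). The collagen-binding proteoglycan Dcn, the only tested stroma marker, rose from 0.665 ± 0.32 to 2.12 ± 0.15 FPKM. Of the immune list, Pecam1 (4.51 ± 0.52 and 5.57 ± 1.12), C1qb (3.29 ± 0.52 and 2.9995 ± 0.20) and Cd68 (0.807 ± 0.50 and 1.32 ± 1.45) did not pass, Tek fell (1.85 ± 0.38 to 0.874 ± 0.24) and H2-Aa rose (0.811 ± 0.12 to 1.62 ± 0.34). Cd68 was at 3.50 FPKM in Esrp1_KO replicate 3 and at 0.541 to 0.639 in the other Esrp1_KO libraries. The epithelial marker Cdh1, 22.7 ± 1.64 and 21.4 ± 2.84 FPKM, did not pass, and Cldn4 fell (4.19 ± 1.29 to 1.67 ± 0.60). Single libraries stood apart. WT replicate 1 held 99 genes at 1 FPKM or more and over 8-fold above every other library, against 2 to 23 in the others, and Esrp1_KO replicate 3 held Lyz2 at 5.44 FPKM, against at most 0.728 elsewhere. With neither of these 2 libraries, 2026 genes passed (791 higher, 1235 lower).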

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

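The tests of scaling, of replicate numbers on mitochondrial transcripts, of a common nuclear total and of cells of other types were chosen after the data were seen; the others named here were written before their result was seen. A group of 4 libraries is listed here where its highest or lowest value stood apart from the rest by Dixon's gap-to-range ratio. Chance alone sets apart about 1 group in 20, or 8.9 of the 178 groups examined, and 9 were found. In WT, Atp6v1g1 was at 10.6 FPKM in replicate 1 against 14.2 to 14.7 in the other libraries, and Ndufv1 at 1.46 in replicate 1 against 0.987 to 1.06. Zp1 was at 19.4 FPKM in WT replicate 3 against 33.3 to 34.3, and Pabpc1l at 6.02 in that library against 6.46 to 6.52. WT replicate 4 had mt-Co1 at 2988 FPKM against 2719 to 2723. In Esrp1_KO replicate 1, Sqstm1 was at 32.7 FPKM against 19.8 to 20.5, Ccdc50 at 4.13 against 6.10 to 6.50, and Zar1 at 340.4 against 244 to 247. Esrp1_KO replicate 3 had Slc25a13 at 2.05 FPKM against 0.830 to 1.01. Among genes below the expression filter, which the main comparison does not test, Psat1 was at 7.38 FPKM in WT replicate 1 and at most 0.0410 elsewhere, Esrp2 at 0.734 FPKM in that library and at most 0.161 elsewhere, and Lyz2 at 5.44 FPKM in Esrp1_KO replicate 3 and at most 0.728 elsewhere.

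The fall of mitochondrially encoded transcripts was weighed against scaling, shared handling and capture. Over 6 scalings the median log2 fold change of the list stayed between −2.02 and −1.81. Over the 4 replicate numbers, taken as pairs, it stayed at or below −1.39 (lowest −2.32). These scalings moved the median of all genes only to between −0.115 and 0.053, so the first result was close to fixed in advance. It shows only that shifts of this size are too small to be the whole source. The fall was seen in each pair, which argues against handling of a single pair as the whole source. These transcripts were already known to differ between the groups when the pairs were examined. Handling that differed by genotype in every pair was not tested and could give the same values. Weaker capture of RNAs with short or no poly(A) tails may contribute and stays open. Of 44 listed replication-dependent histone genes, which mostly lack tails, 6 passed the filter, with a median of −0.035. The bootstrap 95% interval of −0.79 to 0.79 is too wide to decide. Priming was on poly(A) tails, so the 6 genes seen may be those with tails and are a poor control. A lower mitochondrial RNA content of Esrp1_KO eggs is the biological alternative, untested beyond this comparison.

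The rise of nuclear respiratory chain transcripts was not accounted for by length, GC content or expression level. With smooth trends on these removed, the list's median lay at the 100th percentile, above all 10000 random lists matched on exon length and level, with 42 of 42 genes having a value. With a common total of nuclear genes, which takes the loss of mitochondrial reads out of the total, the median was 0.36, against 0.40 as deposited. Mitochondrial transcripts held only 5.20% of the summed FPKM in WT and 1.33% in Esrp1_KO, so this outcome was close to fixed in advance. It shows only that their loss is too small to be the whole source. Over the 4 replicate numbers the list's median was 0.24 or more (highest 0.65). The values argue against the trends and against handling of a single pair as the whole source. Handling that differed by genotype in every pair was not tested here either. A genotype effect is a hypothesis that stays open, as does the correlation between members, with which the list test no longer passed (adjusted p = 0.538).

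Transcripts of other cells in single libraries were weighed last, from marker lists written after WT replicate 1 and Esrp1_KO replicate 3 had drawn attention. Of 14 cleavage-stage embryo genes detected at 0.5 FPKM or more and not seen beforehand, 85.7% (12) had their highest value in WT replicate 1. With those seen beforehand it was 20 of 22, although 10 of the 22 reached 0.5 FPKM in other libraries too. No rate by chance was computed. Sequence shared between listed genes of a family, such as Trim43a and Trim43b, was not checked, so they may not count as separate genes. WT replicate 1 also had the fewest genes at 0 (4813) and the most at 0.1 FPKM or more (14853), so low genes may peak there more often. Trim43a (47.7 FPKM, 0 elsewhere), Obox6 (40.3, at most 0.421 elsewhere), Trim43b (37.0), Alppl2 (23.6) and Pramel7 (21.1) led, so RNA of cleavage-stage embryos is a candidate source; blastocysts are not, since Krt8 and Krt18, abundant there, were listed at 0 FPKM in that library. In Esrp1_KO replicate 3, RNA of macrophages may be present. There 50% (4 of 8) of the detected macrophage genes not seen beforehand were highest, and 14 of 19 with the others. Ctsk led (11.01 FPKM, at most 0.0797 elsewhere). Only 19 of 33 listed genes reached 0.5 FPKM in any library, and 11 of the 19 did so in other libraries. C1qb was at 2.73 there and 2.71 to 3.90 elsewhere. Mrc1 (0.422 there, 3.05 to 3.93 in WT) and Laptm5 (0.976 there, 1.41 to 2.19 in WT) were lower than in WT. The immune markers Adgre1 and Ptprc reached at most 0.0124 and 0.0838 FPKM in any library, so macrophages are only a candidate source. Whether this RNA came from cells in the tube or from a later step was not tested, and the design names no biological reason for it.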

How the results depend on the processing

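The voom fit, the runs on replicates 1 and 4, on replicates 2 and 3 and without both doubted libraries, and the common nuclear total were chosen after the data were seen. Of the 2961 calls, 2579 also passed with TMM scaling and 1355 with replicates 2 and 3 alone. No gene among those named by the rule changed sign, a record that leaves out Eif1ad and Sp110, whose sign turned and which were dropped with their list. No list passed in opposite directions, although the medians of 8 lists changed sign under another scaling. Of 2008 alternative values of named genes 17 lost a call and 2 gained one, as did 10 and 14 of 670 values of lists. Lost calls include Syce2, Ndufv1 and Hspa5 with replicates 1 and 4 alone, Nlrp4c, Nlrp4a, Stag1, Tpx2, Ndufv1, Ctnna1 and Marf1 with replicates 2 and 3 alone, and Tpx2 without both doubted libraries. Testing only genes with a mean of at least 5 FPKM gave 1664 genes (668 higher, 996 lower; 177 and 319 by at least 1), since fewer genes were tested. Counts of changes of at least 1 grew to 457 and 906 with a pseudocount of 0.1, and to 474 and 948 with voom on the recovered reads, both of which shrink low genes less. Replicates 1 and 4 alone gave 675 higher genes, and replicates 2 and 3 alone 1448 genes (569 higher, 879 lower), from 4 libraries each. List calls, 4 as reported, were 7 with no filter, 2 at 5 FPKM, 7 with replicates 1 and 4 alone, 7 with replicates 2 and 3 alone and 0 with an estimated correlation; the cause was not tested. Leaving out 1 library gave 2383 to 2866 genes, 883 to 1093 higher, 1477 to 1838 lower, 281 to 309 and 558 to 616 by at least 1, 3 to 7 list calls (7 without Esrp1_KO replicate 1), an Esrp1 log2 change of −2.18 to −1.998 and a difference of −507 to −353 detected genes. The difference in detected genes was −460 as reported, −555.5 at 0.1 FPKM (exact permutation p = 0.171), −177 at 5 FPKM (0.0571), and −460 in the paired sign-flip test (0.125). All of these used FPKM as deposited, and no other scaling was tried for them. The replicate block changed no other call of a named gene or list. Depth was not tested by downsampling. Esrp1 rested on at least 417 reads per library, and 1 FPKM in a transcript of 1 kb is 24.9 to 32.3 reads.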

Other observations

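Several genes outside the fixed lists that act on mitochondrial nucleic acids were lower in Esrp1_KO. Of 26 tested genes for mitochondrial transcription, RNA processing and DNA maintenance, a list written after the main comparison, 14 fell and 1 rose, with a median log2 fold change of −0.45; the list did not pass (camera adjusted p = 0.114 over 6 lists with a preset correlation, adjusted p = 0.237 with an estimated correlation). The termination factor genes Mterf1a (4.15 ± 0.63 to 0.292 ± 0.10 FPKM) and Mterf1b fell most. Tfam, which packages and transcribes mitochondrial DNA (2.57 ± 0.43 to 1.12 ± 0.24), the transcription factor Tfb2m (6.93 ± 1.49 to 3.61 ± 0.46), the RNase P subunit Trmt10c (17.0 ± 2.54 to 8.11 ± 1.58) and the nucleoside kinase Dguok (13.3 ± 2.10 to 6.40 ± 1.29) also fell (limma), while the RNA granule protein Grsf1 rose (9.59 ± 2.53 to 21.4 ± 2.14). Of 43 mitochondrial ribosomal protein genes 8 fell and 3 rose, among them Mrps9, which rose from 2.41 ± 0.53 to 6.79 ± 0.75 (camera adjusted p = 0.887).

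Tests of 3 hypotheses follow; those on growing-oocyte and dormant transcripts were chosen after the result was seen. Lower mRNA of core mitochondrial transcription factors may go with the lower mitochondrial transcripts, but the 5 genes named for this in advance did not decide it. Their median log2 fold change was −0.226, past the bound of −0.25 set in advance as counting against the hypothesis, but not by more than their spread, with Tfb2m at −0.77, Tfam at −0.75, Lrpprc at −0.11, and Tefm at −0.23 and Polrmt at 0.15, both near the floor. The first run of this test used only the 3 genes tested in the main comparison (median −0.75) and fitted the hypothesis. Using all 5, and counting their spread, were choices made after those values were seen.

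Retention of growing-oocyte transcripts with lower values of mRNAs recruited at maturation could mark eggs that completed maturation only in part. The oocyte identity list with Zp1, Zp2 and Zp3 (31 genes, median 0.21) lay at percentile 96.55 of 10000 random lists matched on mean level, short of the bound set for it. The 3 zona genes were added after they were seen to rise, so this value decides nothing. The dormant mRNA list (18 genes, median −0.17) lay at percentile 5.73, short of its bound, so the question stays open.

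Sequence of another strain carried with the targeted allele could change genes near Esrp1. Of 39 tested genes within 10 Mb on chromosome 4, 18 (46.2%) passed, 6 higher and 12 lower, against 36.9% of all other tested genes (odds ratio 1.47, 95% interval 0.74 to 2.90, Fisher's exact p = 0.246), which leaves the question open. The prediction, written in advance, put its bound at an odds ratio of 1.5, so the value alone would count against the hypothesis. Judging by the interval was decided after the value was seen.

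Counted alike, the splits argue against chance for the difference between the genotypes as a whole. The share of 1 in 35 is the lowest possible, and each other split mixes the genotypes, which holds its count down. Only 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, gave as many genes, 2961, and the highest of the others gave 1. Of the 8 splits that part all 4 same-numbered pairs, the real one included, the others gave 0 (limma; at most 441 at an unadjusted p under 0.05, against 3733 for the real split), but 8 splits are too few for a share under 5%. The split of replicates 1 and 4 from replicates 2 and 3 gave 0 as well, with 933 at an unadjusted p under 0.05.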
